A study of Homo sapiens with 127 samples.

How the data were processed

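Promoter read counts were taken from 254 annotation files, one for each of 127 libraries and each of 2 window sizes, with windows reaching 1 kb and 2.5 kb to either side of the transcription start (hg19). The counts are whole numbers deposited by the authors, unnormalized, as their values show. CASAVA 1.8.2, Bowtie2 2.1.0, MACS2 2.1.0.20141030 and featureCounts (no version) are named per the submitters' processing notes, and their roles and settings are not given in the sources used here. The files also hold CPM and FPKM values deposited by the authors, which were not used. CPM equalled the count over the total of the file.

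Genes were identified by Entrez ID, and 22107 of 23459 genes took their symbol from the files. A RefSeq gene table named a further 1337 by ID and 15 stayed unnamed. Windows on the Y chromosome and on contigs outside chromosomes 1 to 22 and X were left out, with a gene of X inactivation and its antisense gene. Windows of separate genes with identical coordinates (557 of 1 kb radius and 515 of 2.5 kb) held 0 reads in all libraries. Other overlapping windows had a median of 4.27 reads against 15.1 in windows without overlap (1 kb) and 3.91 against 36.1 (2.5 kb), so reads falling in overlapping windows appear not to have been counted. The 1 gene named from such a window is given with that fact.

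One window per gene was tested, the one with the highest mean CPM over all libraries of the mark. Windows of 1 kb radius served H3K4me2, H3K4me3 and input, and windows of 2.5 kb radius served H3K27me3. Genes needed about 10 reads at the median library size in at least 4 libraries (3 in H3K27me3) and 15 in total, which left 17833 genes for H3K4me2, 20121 for H3K4me3, 19723 for H3K27me3 and 20219 for input. Library totals were scaled with TMM factors (30% of ratios and 5% of abundances trimmed), from 0.847 to 1.09 in H3K4me2, 0.887 to 1.08 in H3K4me3 and 0.825 to 1.46 in H3K27me3. Factors and filter were re-implemented after the published methods. Counts were tested with limma voom 3.58.1 in R 4.3.3 (with statmod 1.5.0 and the package data.table, version 1.17.8), with robust empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested, called at 0.05. The 8 groups of a mark shared 1 fit, and contrasts compared each day with D0 within a subset, memory with naive cells at each day, and the change from D0 between the subsets over the 3 later days (the interaction). The design had planned edgeR quasi-likelihood tests, and limma voom was used instead of edgeR because the counts sit with other values in a text column of the files, whose unit was therefore not recorded as counts.

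Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, over 22 lists of 302 genes. Beside each camera result stands the adjusted p with a correlation estimated from the libraries, with which 43 list results lost their call. Fry, which does not compare a list with other genes, was also run. Results are given for the Treg, Th1, Th2, Th17, naive T cell, memory and effector T cell, early activation, cytokine and chemokine, cell cycle, interferon-stimulated, inhibitory receptor, developmental regulator, housekeeping and monocyte marker lists.

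Genes named were, per mark and contrast, up to 12 rises and 12 falls with the largest fold change among those called, with at least 20 reads on average in the higher group and the same direction in every donor, and called members of the lists. Some genes that met the rule are not reported here. This rule, the comparisons, windows, lists and most alternatives were set before the data were examined. The limits for libraries in doubt, the sample quality weights and the genes marked as named after their values were seen came afterwards. In the text n is the number of libraries, one per donor. Levels in CPM were computed from the counts here.

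The same 4 donors gave every group (3 of them H3K27me3 at memory D14), so donor numbers pair the libraries per the labels. Over the 2000 most abundant genes the deviations of libraries with the same donor correlated with medians from -0.24 to 0.38 across contrasts. Donor as a block was run as an alternative, as fixed in the design. Other alternatives were median-of-ratios factors, no factors, loess offsets on abundance, no filter, the other window, all promoter windows, fits of the groups of a contrast alone, adjustment by input, and leaving out each donor.

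The pipeline was tested on simulated counts for naive D5 against D0 with 200 changed genes. In H3K4me2 (17411 genes) it called 1.49% of genes changed 1.5-fold, 40% of those changed 2-fold and 64.1% of those changed 4-fold. In H3K4me3 (19631 genes) the shares were 3.03%, 9.09% and 43.1%, in H3K27me3 (19638 genes) 0%, 1.49% and 60.6%, and in input (20101 genes) 0%, 0% and 1.52%. The raised cell cycle list was found in all. Unchanged genes called were 5, 2, 1 and 0. No replicate was a copy of another in its group, since pairs differed by at least 1.19 times the counting variance.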

Results

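Promoter chromatin was profiled in human CD4 T cells from 4 donors, numbered 1 to 4. Naive and memory cells were sampled at rest (D0) and 1, 5 and 14 days after activation with beads carrying antibodies to CD3 and CD28 (D1, D5 and D14). IL-2 is recorded from day 5 and may add to D14 changes. Each sample gave chromatin immunoprecipitation libraries for H3K4me2, H3K4me3 and H3K27me3 and an input library without immunoprecipitation. Every group of mark, subset and day held 4, except H3K27me3 memory D14 with 3, 127 libraries in all. Reads in promoter windows per library had a median (range) of 1544012 (662347 to 2744174) for H3K4me2, 1323752 (443416 to 2550286) for H3K4me3, 839562 (565359 to 1595910) for H3K27me3 and 510169 (108481 to 927050) for input. These totals cover promoter windows only, so sequencing depth is not known.

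The share of promoter reads in CpG island windows had a median (range) of 77.4% (68.6% to 82.3%) in H3K4me2 and 79.4% (60.7% to 84.5%) in H3K4me3, against 48.9% (40% to 60.1%) in H3K27me3 and 46.3% (39.5% to 63.3%) in input, so that the ranges of H3K4me3 and input overlapped. H3K27me3 stood above input at developmental regulators, where 30 genes held 0.44% of promoter reads at the median (0.146% to 0.701%) against 0.0856% (0.0657% to 0.112%). Libraries also differed in how many windows of 1 kb radius held no read. The median share was 11.7% (4.83% to 41.1%) in H3K4me2, 9.8% (4.53% to 51.5%) in H3K4me3, 11.4% (6.29% to 36%) in H3K27me3 and 6.62% (4.81% to 40.9%) in input. Libraries with over 30% of windows at 0, or in the H3K4 marks with under 70% of promoter reads in CpG island windows, are called libraries in doubt below, a limit chosen after the data were examined. They were H3K4me2 in naive cells at D1 (donors 1 and 4) and D5 (donor 2) and in memory cells at D0 (donors 2 and 3) and D1 (donor 1). In H3K4me3 they were naive D0 (donor 1), D1 (donors 1 and 4) and D14 (donor 2) and memory D0 (donors 1 and 3), D1 (donors 1 and 4) and D14 (donor 1). One was in H3K27me3 (memory D14, donor 4) and 3 in input (naive D1 of donors 1 and 4, memory D1 of donor 4).

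**Figure D1:**
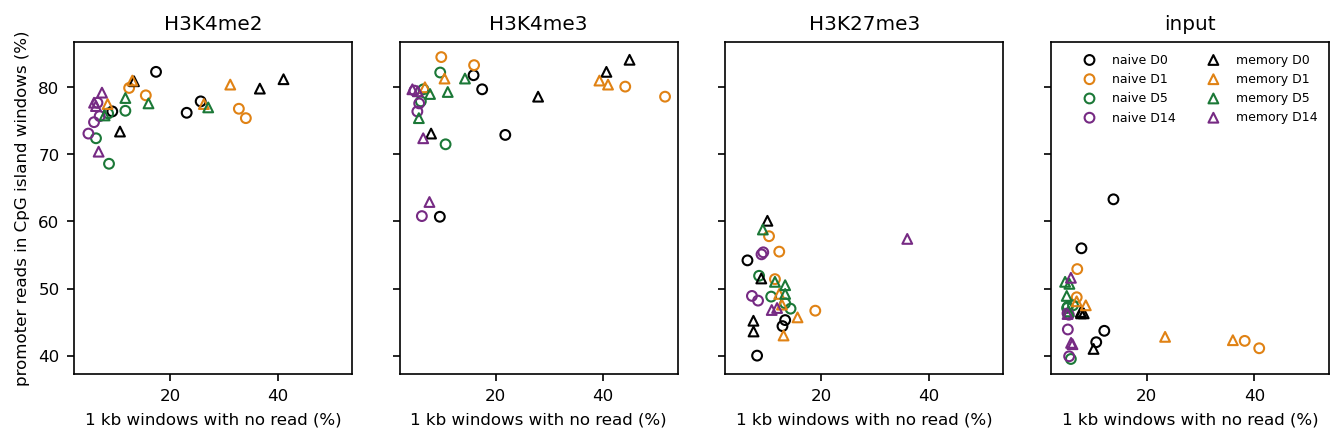
Each point is 1 library, with the share of 1 kb radius promoter windows without a read on the x axis and the share of promoter reads in CpG island windows on the y axis, both in percent, by mark, subset and day. Libraries with many empty windows lie to the right, among them 1 memory D14 library of H3K27me3 at 36% of windows.

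Below, the value after a gene symbol is the log2 fold change of its promoter ± the standard error from limma voom, with 4 libraries per group unless stated. Promoters called had a Benjamini-Hochberg adjusted p under 0.05. Levels are means ± SD in CPM, promoter reads scaled to the same library total. For gene lists, calls adjusted over the genes of the list alone follow in brackets where they differ, and the camera adjusted p is followed by the one with a correlation estimated from the libraries. The followed genes met the rule for naming genes and were tracked through the other settings, and some of them are not named here. Totals are also given as a range over 10 other settings, with the share of higher calls where there were at least 10 calls. The settings were median ratios (median-of-ratios factors), unscaled, loess offsets, no filter, donor as a block, the other window, all windows, only the 2 groups fitted, input (its change subtracted) and sample quality weights. Values without the libraries in doubt are given only where the groups compared hold such a library. The input libraries gave 0 calls in each of the 10 comparisons and in the interaction (limma voom), with 30 to 3145 promoters at an unadjusted p under 0.05. Leaving out a donor raised the largest of these counts to 161 (memory D5). Counts in the marks moved by large factors with the donor left out, so each is given with that range.

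**Figure D2:**
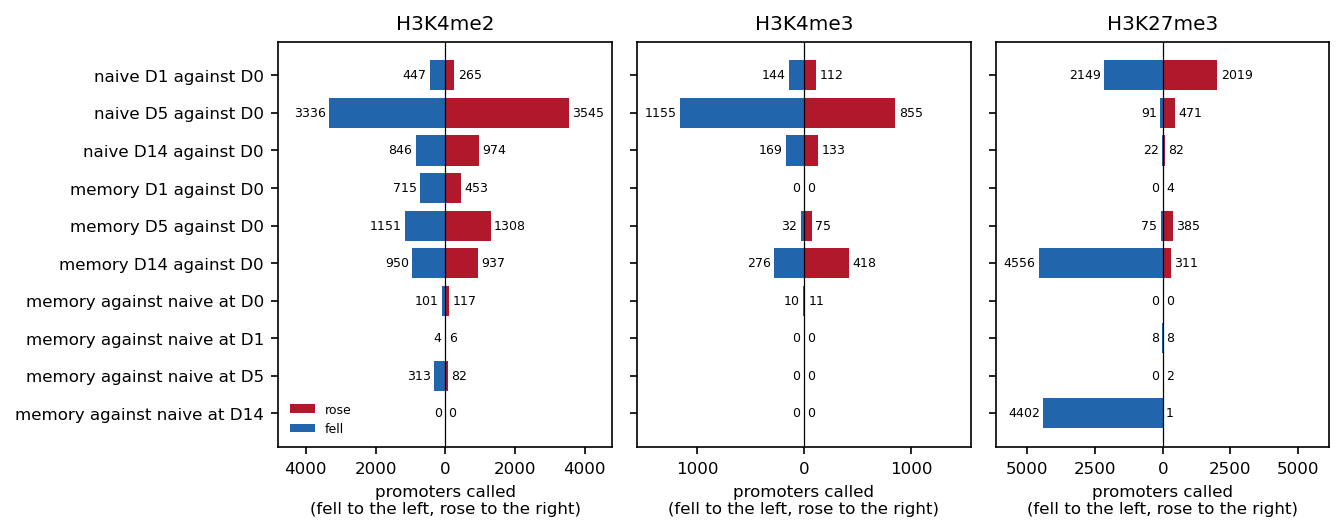
Bars show the number of promoters called higher (red, right) and lower (blue, left) in each comparison for the 3 marks, at an adjusted p under 0.05 with all libraries. In H3K4me2 naive cells at D5 had 3545 higher and 3336 lower, and in H3K27me3 the bars of memory D14 (4556 lower) rest on a group with 1 library of 36% empty windows.

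The activation of naive cells was followed first in H3K4me2, a mark of active and poised promoters. At D1 the largest rises included ZBED2 (4.37 ± 0.92), IL1R2 (4.15 ± 0.93), FURIN (3.37 ± 0.7), ASCL2 (2.82 ± 0.72) and IL23R (2.77 ± 0.66). ZBED2 went from 8.76 ± 8.9 to 86.5 ± 24.8 CPM (SD, n = 4 and 4) (adjusted p 0.00871). Rises were also called at TNFRSF18 (2.26 ± 0.4), TNFRSF9 (1.93 ± 0.35), CCR4 (1.38 ± 0.24), LAG3 (1.34 ± 0.29), TBX21 (1.13 ± 0.31) and KDM6B (1.27 ± 0.24). Falls included POGZ (-2.11 ± 0.61), ZNF736 (-1.65 ± 0.43), DAD1 (-1.38 ± 0.25), RNU11 (-1.25 ± 0.23), IFIT3 (-1.22 ± 0.25), MYC (-1.14 ± 0.2), EGR2 (-1.08 ± 0.24) and CD3E (-0.83 ± 0.21). Adjusted by the change in input, the directions of DAD1, MYC, EGR2 and the Treg list turned, and with the window of 2.5 kb radius that of IL23R did. Of 10 regulatory T cell (Treg) genes, 3 rose and 0 fell (5 and 0 over the list alone), with a median of 0.50 (camera adjusted p 0.0027, 0.0235 estimated). The interferon-stimulated list stood lower in camera, adjusted p 0.0027, 0.2 estimated, with 0 genes up and 2 down of 16 (0 and 3 alone) and a median of -0.39. Among 10 housekeeping genes the median was -0.46, and 0 were called up and 1 down (camera adjusted p 0.00788, 0.0313 estimated). At D1, 265 promoters were called higher and 447 lower of 17833 tested in this mark, and the total ran from 29 (without donor 3) to 1141 (without donor 4). The counts were 78 and 14 without the libraries in doubt, 421 and 670 with donor as a block, 304 and 257 with median ratios, 363 and 159 unscaled and 237 and 120 with loess. Other settings gave 0 (input) to 1091 (block), 35.4% to 81.6% higher. Of 19 followed genes, 3 (CCR4, KDM6B and MYC) stayed called with each donor left out and 10 without the libraries in doubt.

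At D5 H3K4me2 in naive cells rose at LINC00521 (5.91 ± 1), EBI3 (5.60 ± 0.99), EYA2 (5.55 ± 1.3), CSF2 (5.46 ± 1.2), OCSTAMP (5.38 ± 1.5) and TREM1 (5.30 ± 1). EBI3 went from 1.88 ± 1.94 to 78.6 ± 26.3 CPM (SD, n = 4 and 4) with an adjusted p of 7.78e-05. So it did at GZMB (4.33 ± 0.81), IL4 (3.65 ± 0.72), IL5 (3.52 ± 0.92), IL13 (3.17 ± 0.96) and TNFRSF18 (2.72 ± 0.39). The genes PPIP5K2 (-2.38 ± 0.76), IFI44 (-2.23 ± 0.73), CD69 (-1.81 ± 0.63), IFI44L (-1.79 ± 0.47), SATB1 (-1.68 ± 0.57), PRDM1 (-1.10 ± 0.25), IKZF2 (-1.02 ± 0.34) and CCR7 (-0.68 ± 0.17) fell. Among 21 cytokine and chemokine genes the median was 1.64, and 11 were called up and 0 down (12 and 0 alone) (camera adjusted p 0.00222, 0.171 estimated). Of 11 Th2 genes, 6 rose and 0 fell, with a median of 1.51 (camera adjusted p 0.0746, 0.171 estimated). Among 10 Treg genes the median was 1.05, and 5 were called up and 2 down (camera adjusted p 0.0637, 0.171 estimated). The naive T cell list stood lower in camera, adjusted p 0.0384, 0.187 estimated, with 1 genes up and 8 down of 16 (1 and 9 alone) and a median of -0.66. Of 16 interferon-stimulated genes, 0 rose and 6 fell, with a median of -0.38 (camera adjusted p 0.0147, 0.171 estimated). In all, 3545 promoters were called higher and 3336 lower, and the total ran from 3138 (without donor 2) to 6849 (without donor 1). The counts were 4294 and 2534 with median ratios and 4832 and 2081 unscaled. By setting the total ran from 30 (input) to 8328 (all windows), 46% to 100% higher. Among 20 followed genes, 12 stayed called with each donor left out and 18 without the libraries in doubt.

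At D14 naive cells were higher in H3K4me2 than at rest at EYA2 (5.58 ± 1.3), PMCH (5.15 ± 1.5), OMD (4.96 ± 0.91), HRH4 (4.73 ± 0.78), LINC00521 (4.59 ± 1) and CSF2 (4.11 ± 1.2). Also higher were CCL5 (2.63 ± 0.5), CCR8 (2.64 ± 0.47), CXCR6 (1.93 ± 0.25), IL4 (3.47 ± 0.73) and GZMB (3.39 ± 0.83). The genes HOXA9 (-3.42 ± 0.74), UNCX (-3.25 ± 0.91), GLYATL1 (-3.02 ± 0.52), HOXD9 (-2.47 ± 0.55), CLDN2 (-2.26 ± 0.56), ZNF223 (-2.16 ± 0.28) and CCR7 (-0.49 ± 0.16) were lower, CCR7 in 3 of 4 donors and the others in 4. The memory and effector T cell list stood higher in camera, adjusted p 7.76e-06, 0.0206 estimated, with 8 genes up and 0 down of 18 (9 and 0 alone) and a median of 0.63. Of 21 cytokine and chemokine genes, 7 rose and 0 fell (11 and 0 alone), with a median of 1.84 (camera adjusted p 3.46e-06, 0.0302 estimated). Among 13 Th1 genes the median was 0.73, and 5 were called up and 2 down (6 and 2 alone) (camera adjusted p 0.0115, 0.0259 estimated). Of 11 Th2 genes, 6 rose and 0 fell (6 and 1 alone), with a median of 2.06 (camera adjusted p 0.00946, 0.0259 estimated). Among 10 Treg genes the median was 0.65, and 4 were called up and 0 down (5 and 0 alone) (camera adjusted p 0.00946, 0.0259 estimated). Of 26 cell cycle genes, 8 rose and 0 fell (10 and 0 alone), with a median of 0.34 (camera adjusted p 0.00946, 0.0778 estimated). Against D0, 974 promoters were called higher and 846 lower, and the total ran from 215 (without donor 2) to 2099 (without donor 1). The counts were 1139 and 486 with median ratios and 1238 and 433 unscaled. Settings moved the total from 3 (input) to 2606 (weights), 41.1% to 74.1% higher. Here 9 of 19 followed genes stayed called with each donor left out.

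In memory cells at D1, H3K4me2 rose at LGALS14 (3.54 ± 0.99), EBI3 (3.14 ± 0.85), PPL (2.98 ± 0.77), GZMB (2.63 ± 0.72), TNFRSF18 (1.44 ± 0.29), LTA (1.16 ± 0.2) and FOS (0.82 ± 0.17), GZMB in 3 of 4 donors. It fell at TSGA13 (-3.02 ± 0.82), WDR49 (-2.89 ± 0.75), KHDRBS2 (-2.26 ± 0.6), DHX36 (-1.61 ± 0.36), CPA6 (-1.61 ± 0.48), IFIT3 (-0.92 ± 0.24) and RSAD2 (-0.86 ± 0.23), IFIT3 in 3 of 4 donors. Adjusted by the change in input, FOS and CPA6 turned direction. Of 10 Treg genes, 5 rose and 0 fell, with a median of 0.74 (camera adjusted p 0.0263, 0.0907 estimated). The interferon-stimulated list stood lower in camera, adjusted p 0.0167, 0.328 estimated, with 0 genes up and 3 down of 16 (0 and 6 alone) and a median of -0.34. Here 453 promoters were called higher and 715 lower, and the total ran from 4 (without donor 1) to 3022 (without donor 4). The counts were 3 and 0 without the libraries in doubt, 809 and 1330 with donor as a block, 1090 and 375 unscaled and 502 and 472 with loess. Across settings it ran from 9 (input) to 2139 (block), 24.2% to 86.9% higher. Of 14 followed genes, 0 stayed called with each donor left out and 0 without the libraries in doubt.

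At D5 memory cells gained H3K4me2 at ECSCR (5.01 ± 0.98), LGALS14 (4.96 ± 0.94), EBI3 (4.79 ± 0.81), LINC00521 (4.79 ± 0.92) and KCTD10 (4.67 ± 0.94) and at GZMB (3.58 ± 0.69), IL1RL1 (2.51 ± 0.49), LAG3 (2.11 ± 0.27) and IL23R (1.81 ± 0.4). It fell at GAPT (-5.53 ± 1.1), HGF (-4.91 ± 1.1), CD36 (-4.62 ± 1.2), HP (-4.36 ± 1), LYZ (-4.33 ± 0.82), MS4A3 (-4.26 ± 0.91), FPR2 (-4.24 ± 1) and FCN1 (-4.08 ± 1.2). LYZ went from 37.1 ± 22.2 to 2.82 ± 2.51 CPM (SD, n = 4 and 4). LYZ and MS4A3 were also higher in memory than naive cells at rest, where monocytes are weighed below. These falls may therefore not be changes within memory T cells. Falls were smaller at IFIT2 (-1.23 ± 0.27) and IRF8 (-0.87 ± 0.29), IRF8 in 3 of 4 donors. Among 12 monocyte marker genes the median was -2.83, and 1 were called up and 5 down (1 and 8 alone) (camera adjusted p 0.00187, 0.151 estimated). Of 21 cytokine and chemokine genes, 9 rose and 0 fell (13 and 0 alone), with a median of 1.33 (camera adjusted p 6.53e-05, 0.0526 estimated). Among 10 Treg genes the median was 0.86, and 4 were called up and 0 down (5 and 0 alone) (camera adjusted p 0.00128, 0.0109 estimated). The inhibitory receptor list stood higher in camera, adjusted p 0.00626, 0.0331 estimated, with 3 genes up and 0 down of 8 (4 and 0 alone) and a median of 0.77. Of 18 memory and effector T cell genes, 6 rose and 0 fell (7 and 0 alone), with a median of 0.35 (camera adjusted p 0.0014, 0.0466 estimated). At D5 1308 promoters were called higher and 1151 lower, and the total ran from 816 (without donor 3) to 2191 (without donor 4). The counts were 708 and 698 without the libraries in doubt and 1918 and 720 unscaled. Other settings gave 202 (input) to 3063 (block), 46.9% to 83.7% higher. Here 12 of 19 followed genes stayed called with each donor left out and 17 without the libraries in doubt.

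At D14 memory cells were higher than at rest at OR6X1 (4.91 ± 1.5), LINC00521 (4.24 ± 0.93), CAPN14 (3.71 ± 0.79), TEAD4 (3.40 ± 0.75), LAG3 (1.61 ± 0.28) and FOXP3 (1.44 ± 0.41). They were lower at MS4A3 (-3.91 ± 0.87), CSF1R (-3.41 ± 1), AQP9 (-3.40 ± 0.86), FPR2 (-2.99 ± 0.83), CSTA (-2.98 ± 0.8), CLEC4E (-2.90 ± 0.72) and IFIT2 (-0.91 ± 0.27). With the window of 2.5 kb radius CSF1R turned direction, and adjusted by the change in input IFIT2 did. Of 10 Treg genes, 3 rose and 0 fell, with a median of 0.46 (camera adjusted p 0.0808, 0.306 estimated). Among 12 monocyte marker genes the median was -0.91, and 0 were called up and 1 down (0 and 5 alone) (camera adjusted p 0.0248, 0.426 estimated). At D14 937 promoters were called higher and 950 lower, and the total ran from 78 (without donor 2) to 2726 (without donor 4). The counts were 188 and 282 without the libraries in doubt, 1361 and 1484 with donor as a block, 1140 and 759 with median ratios and 1928 and 472 unscaled. By setting the total ran from 4 (input) to 2845 (block), 37.2% to 80.3% higher. Among 14 followed genes, 2 (CEND1 and LAG3) stayed called with each donor left out and 10 without the libraries in doubt. Naive and memory cells shared part of these calls, which came from separate D0 libraries. At D5, 895 promoters rose in both subsets where independent lists would share 260, 824 fell in both against 215, and 28 were called in opposite directions. At D1 both rose at 90 against 6.73 and both fell at 164 against 17.9, and at D14 at 297 against 51.2 and 292 against 45.1.

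In H3K4me3, a mark of active promoters, naive cells at D1 gained most at TNFRSF18 (3.73 ± 0.87), FOSL2 (3.04 ± 0.47), ELOVL7 (2.80 ± 0.75) and NIPAL4 (2.37 ± 0.61). CCR4 (2.00 ± 0.49), TBX21 (1.98 ± 0.44), IRF8 (1.68 ± 0.3) and IL2RA (1.62 ± 0.34) rose as well. Falls were seen at POGZ (-3.01 ± 0.73), BCO2 (-2.99 ± 0.78), EDA2R (-2.93 ± 0.72), FAM65B (-1.96 ± 0.44), IFI6 (-1.87 ± 0.39) and IFIT1 (-1.35 ± 0.25). Of 16 interferon-stimulated genes, 0 rose and 4 fell (0 and 7 alone), with a median of -0.76 (camera adjusted p 1.84e-05, 0.08 estimated). The early activation list stood higher in camera, adjusted p 7.36e-04, 0.04 estimated, with 2 genes up and 1 down of 20 (5 and 1 alone) and a median of 0.21. Among 10 Treg genes the median was 0.60, and 2 were called up and 0 down (4 and 1 alone) (camera adjusted p 0.00401, 0.0926 estimated). At D1 112 promoters were called higher and 144 lower of 20121 tested in this mark, and the total ran from 6 (without donor 3) to 550 (without donor 4). The counts were 185 and 128 unscaled and 303 and 241 with loess. Settings moved the total from 1 (2 groups or input) to 544 (loess), 17.1% to 65.8% higher. Of 17 followed genes, 0 stayed called with each donor left out and 11 without the libraries in doubt.

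At D5 naive cells gained H3K4me3 at VWA1 (4.52 ± 0.8), LINC00521 (4.44 ± 0.88), AHRR (4.43 ± 0.78), TNFRSF18 (4.18 ± 0.86), EBI3 (3.95 ± 0.8), STC2 (3.84 ± 0.54), CYP1B1 (3.84 ± 0.79), ZBED2 (3.83 ± 0.74) and TUBB3 (3.77 ± 0.71). CSF2 (3.55 ± 1), LAG3 (2.98 ± 0.7), TBX21 (2.15 ± 0.44) and RRM2 (1.52 ± 0.28) rose too, RRM2 in 3 of 4 donors. Losses were largest at ARHGAP32 (-3.08 ± 0.96), IFI44 (-3.01 ± 0.88), SAMD3 (-2.79 ± 0.6), ESR1 (-2.65 ± 0.66), ZBTB18 (-2.63 ± 0.44) and GPA33 (-2.54 ± 0.48), with IFIT3 (-2.14 ± 0.44) and NELL2 (-0.81 ± 0.21) among the genes of the lists. Without donor 2, ARHGAP32 turned to 1.12. The interferon-stimulated list stood lower in camera, adjusted p 1.36e-07, 0.0667 estimated, with 0 genes up and 7 down of 16 (0 and 8 alone) and a median of -0.64. Of 16 naive T cell genes, 0 rose and 6 fell (0 and 10 alone), with a median of -0.69 (camera adjusted p 5.37e-05, 0.217 estimated). Among 26 cell cycle genes the median was 0.74, and 9 were called up and 0 down (14 and 1 alone) (camera adjusted p 9.19e-04, 0.217 estimated). At D5, 855 promoters were called higher and 1155 lower, and the total ran from 1 (without donor 3) to 2577 (without donor 1). The counts were 2083 and 2375 without the libraries in doubt, 1217 and 1035 with median ratios, 1495 and 748 unscaled and 608 and 473 with loess. Across settings it ran from 0 (input) to 2252 (median ratios), 22.4% to 66.7% higher. Here 1 of 21 followed genes (ZBTB18) stayed called with each donor left out and 21 without the libraries in doubt.

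At D14 naive cells were higher in H3K4me3 at LINC00521 (4.40 ± 0.87), AHRR (4.22 ± 0.78), FBN1 (3.99 ± 0.76), EYA2 (3.98 ± 0.92), TUBB3 (3.85 ± 0.7), NCF4 (3.55 ± 0.67) and MKI67 (1.29 ± 0.25). They were lower at ZNF223 (-2.21 ± 0.35), EDAR (-1.99 ± 0.36), ZBTB18 (-1.70 ± 0.36) and LGMN (-1.48 ± 0.33). Of 26 cell cycle genes, 4 rose and 0 fell (9 and 0 alone), with a median of 0.58 (camera adjusted p 1.58e-04, 0.189 estimated). Among 18 memory and effector T cell genes the median was 0.92, and 2 were called up and 0 down (9 and 0 alone) (camera adjusted p 4.61e-04, 0.189 estimated). The interferon-stimulated list stood lower in camera, adjusted p 0.00102, 0.245 estimated, with 0 genes up and 1 down of 16 (0 and 2 alone) and a median of -0.38. By D14, 133 promoters were called higher and 169 lower, and the total ran from 0 (without donor 3) to 1316 (without donor 1). The counts were 599 and 830 without the libraries in doubt, 233 and 167 with median ratios, 212 and 87 unscaled and 120 and 90 with loess. Other settings gave 0 (input) to 400 (median ratios), 9.09% to 75.6% higher. Among 13 followed genes, 0 stayed called with each donor left out and 13 without the libraries in doubt.

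In memory cells at D1 limma voom called 0 promoters in H3K4me3, with 2077 at an unadjusted p under 0.05, up to 7 calls with a donor left out and, with other settings, 0 (7 of them) to 14 (loess). Of 16 interferon-stimulated genes, 0 rose and 0 fell (0 and 5 alone), with a median of -0.42 (camera adjusted p 1.45e-06, 0.12 estimated). Among 10 Treg genes the median was 0.74, and 0 were called up and 0 down (3 and 0 alone) (camera adjusted p 0.00452, 0.145 estimated). At D5 memory cells gained H3K4me3 at GZMB (4.70 ± 1), LINC00521 (4.70 ± 0.83), KCTD10 (4.53 ± 0.84), EBI3 (4.50 ± 0.78), LGALS14 (4.26 ± 0.91) and TNFRSF18 (2.13 ± 0.52). They lost it at HGF (-3.85 ± 0.94), ALDH1A1 (-3.54 ± 0.87), RAP1GAP2 (-1.75 ± 0.27), TLR3 (-1.66 ± 0.33), IFIT2 (-1.62 ± 0.28), IFIT3 (-1.48 ± 0.3), CASP1 (-1.41 ± 0.25) and NLRP3 (-1.32 ± 0.25). The interferon-stimulated list stood lower in camera, adjusted p 9.16e-07, 0.103 estimated, with 0 genes up and 3 down of 16 (0 and 4 alone) and a median of -0.27. At D5, 75 promoters were called higher and 32 lower, and the total ran from 2 (without donor 3) to 105 (without donor 1). The counts were 74 and 132 without the libraries in doubt and 66 and 76 with loess. By setting the total ran from 4 (2 groups) to 281 (all windows), 0% to 100% higher. Of 15 followed genes, 0 stayed called with each donor left out and 11 without the libraries in doubt.

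At D14 the memory cells were higher in H3K4me3 than at rest at LONRF2 (4.46 ± 0.94), LINC00521 (4.25 ± 0.86), PGBD5 (4.10 ± 0.84), FBN1 (3.85 ± 0.79) and TEAD4 (3.64 ± 0.9) and lower at ZNF223 (-1.84 ± 0.36), TLR3 (-1.81 ± 0.33), NLRP3 (-1.79 ± 0.29) and CASP1 (-1.46 ± 0.26). Of 16 interferon-stimulated genes, 0 rose and 5 fell (0 and 7 alone), with a median of -0.70 (camera adjusted p 1.55e-08, 0.0383 estimated). At D14, 418 promoters were called higher and 276 lower, and the total ran from 1 (without donor 3) to 1801 (without donor 2). The counts were 111 and 145 without the libraries in doubt, 99 and 113 with donor as a block, 584 and 210 with median ratios and 535 and 163 unscaled. Settings moved the total from 0 (input) to 1335 (other window), 12% to 97.5% higher. Here 1 of 12 followed genes (NLRP3) stayed called with each donor left out and 6 without the libraries in doubt. Both subsets rose at 40 promoters at D5 (3.19 for independent lists) and fell at 20 (1.84), and at D14 at 34 (2.76) and 55 (2.32).

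H3K27me3, a mark of repressed promoters, rose in naive cells at D1 at NKX2-3 (1.99 ± 0.38), EBI3 (1.98 ± 0.42), PDLIM4 (1.93 ± 0.61), SIX3 (1.92 ± 0.4), SIX2 (1.85 ± 0.39), PAX9 (1.58 ± 0.41) and PAX2 (1.39 ± 0.37). NKX2-3 went from 79.6 ± 38.4 to 289 ± 66.2 CPM (SD, n = 4 and 4) (adjusted p 0.00596). It fell at CLCN3 (-3.51 ± 1), MYCBP2 (-3.32 ± 0.83), GPR18 (-3.26 ± 0.7), MIR155 (-3.22 ± 0.59), XPO1 (-3.08 ± 0.76), ZNF217 (-3.00 ± 0.66) and CSE1L (-2.89 ± 0.46) and at SATB1 (-2.72 ± 0.66), NR4A3 (-2.66 ± 0.87) and IL7R (-2.48 ± 0.78). The MIR155 window (chromosome 21, 26943792 to 26948791, hg19) went from 55.8 ± 17.8 to 5.22 ± 2.22 CPM (SD, n = 4 and 4). Of 30 developmental regulator genes, 18 rose and 0 fell (22 and 0 alone), with a median of 1.23 (camera adjusted p 3.22e-11, 0.299 estimated). At D1, 2019 promoters were called higher and 2149 lower of 19723 tested in this mark, and the total ran from 0 (without donor 1 or 2) to 6884 (without donor 4). The counts were 1149 and 3931 unscaled and 25 and 66 with loess (weighed below). Across settings it ran from 91 (loess) to 5080 (unscaled), 22.6% to 52.3% higher. Of 17 followed genes, 0 stayed called with each donor left out.

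At D5 naive cells gained H3K27me3 at KRT7 (2.09 ± 0.42), CRABP1 (2.05 ± 0.4), PTAFR (2.05 ± 0.3), KLF2 (2.05 ± 0.41), CCR2 (2.01 ± 0.4), GPR25 (2.00 ± 0.35) and IL10 (1.67 ± 0.36). They lost it at DUSP4 (-3.22 ± 0.66), ARID5B (-2.21 ± 0.44), KDM6B (-2.14 ± 0.51), RRM2 (-2.08 ± 0.4), TOP2A (-1.62 ± 0.31), NR4A2 (-1.57 ± 0.39) and IRF8 (-1.20 ± 0.26). Among 20 early activation genes the median was -1.05, and 0 were called up and 2 down (0 and 5 alone) (camera adjusted p 1.69e-04, 0.249 estimated). Of 22 cell cycle genes, 0 rose and 2 fell (0 and 3 alone), with a median of -0.57 (camera adjusted p 0.00308, 0.249 estimated). At D5, 471 promoters were called higher and 91 lower, and the total ran from 2 (without donor 1) to 529 (without donor 4). The counts were 306 and 56 with donor as a block and 2 and 16 with loess. Other settings gave 0 (input) to 2237 (weights), 11.1% to 94.2% higher. Among 16 followed genes, 0 stayed called with each donor left out. At D14 the rises were at GNA11 (2.24 ± 0.52), EFNA1 (2.06 ± 0.48), KCNH3 (2.04 ± 0.39) and EPHA2 (1.88 ± 0.33) and the falls at ASPM (-2.36 ± 0.43), CDC25A (-2.15 ± 0.33), RRM2 (-2.08 ± 0.37), WEE1 (-1.97 ± 0.38), IL12RB2 (-1.85 ± 0.35), MKI67 (-1.66 ± 0.31) and TOP2A (-1.34 ± 0.28). The cell cycle list stood lower in camera, adjusted p 8.18e-07, 0.0566 estimated, with 0 genes up and 3 down of 22 (0 and 5 alone) and a median of -0.62. At D14, 82 promoters were called higher and 22 lower, and the total ran from 0 (without donor 2 or 3) to 24 (without donor 4). The counts were 50 and 29 unscaled and 2 and 44 with loess. By setting the total ran from 42 (input) to 448 (weights), 4.35% to 85.7% higher. Here 0 of 13 followed genes stayed called with each donor left out.

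In memory cells at D1 H3K27me3 rose at 4 promoters. They were ZNRF3 (1.31 ± 0.24), PTPRE (1.28 ± 0.23) and ELOVL3 (1.27 ± 0.23) and TOE1 (4.16), whose window overlaps that of another gene and which was named after its value was seen. With donor as a block the adjusted p was 0.0621 for ZNRF3 and 0.0621 for PTPRE. Without a donor 0 or 1 promoters were called, with other settings 0 (unscaled or 2 groups) to 3465 (weights), 30.8% to 43% higher, and 3795 had an unadjusted p under 0.05. Among 20 early activation genes the median was -0.77, and 0 were called up and 0 down (camera adjusted p 0.00196, 0.258 estimated). At D5 the mark rose at RAP1GAP2 (2.80 ± 0.49), PTAFR (2.75 ± 0.29), CCR2 (2.58 ± 0.38), KLF2 (2.42 ± 0.37), BID (2.37 ± 0.49), MGAT5 (2.1 ± 0.32), IL10 (1.93 ± 0.35), IFIT3 (1.54 ± 0.37) and IRF8 (1.11 ± 0.25). It fell at DUSP4 (-2.83 ± 0.63), SOCS1 (-2.70 ± 0.68), IRF4 (-2.69 ± 0.65), TNFRSF18 (-2.5 ± 0.55), ENO2 (-2.39 ± 0.55), SLC38A1 (-2.20 ± 0.51), S1PR1 (-2.08 ± 0.51) and RRM2 (-1.88 ± 0.39). Of 11 monocyte marker genes, 2 rose and 0 fell (3 and 0 alone), with a median of 0.83 (camera adjusted p 5.31e-04, 0.112 estimated). At D5, 385 promoters were called higher and 75 lower, and the total ran from 78 (without donor 3) to 287 (without donor 1). The counts were 8 and 7 with loess. Settings moved the total from 15 (loess) to 3153 (weights), 53.3% to 86.8% higher. Of 17 followed genes, 6 (CCR2, IL10, KLF2, MGAT5, PTAFR and RAP1GAP2) stayed called with each donor left out. Naive and memory cells both rose at 123 promoters at D5 (9.19 for independent lists), both fell at 10 (0.346) and were opposite at 1.

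At D14 the memory group of H3K27me3 held 3 libraries, 1 of them in doubt and none from donor 2. The rises included RAP1GAP2 (2.56 ± 0.52), PTAFR (1.99 ± 0.32), IFNGR2 (1.83 ± 0.35) and CLCF1 (1.79 ± 0.36) and the falls DUSP4 (-5.41 ± 0.94) and IRF4 (-4.54 ± 0.9), with n = 3 at D14. At D14, 311 promoters were called higher and 4556 lower, and the total ran from 0 (without donor 2 or 4) to 6248 (without donor 1). The counts were 9 and 1 without the libraries in doubt, 19 and 9 with donor as a block, 104 and 136 unscaled and 749 and 1549 with loess. Across settings it ran from 0 (2 groups) to 5977 (all windows), 4.2% to 72.7% higher. Among 8 followed genes, 0 stayed called with each donor left out and 2 without the libraries in doubt. Against naive cells at the same day, 1 promoter was called higher, LOC341056 (0.70 ± 0.25), and 4402 lower, among them IRX4 (-4.07 ± 1.1) and PCDH7 (-3.91 ± 0.99). With donor as a block or without the library in doubt this comparison had 0 calls (limma voom), with 4960 promoters at an unadjusted p under 0.05 in the block fit and 251 without the library, leaving out a donor moved its total from 0 (without donor 2 or 4) to 5224 (without donor 3), and other settings gave 0 (5 of them) to 5673 (all windows), 0% to 0.268% higher.

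In H3K4me2 at rest, memory cells were higher than naive cells at AQP9 (4.99 ± 1), VNN3 (4.80 ± 0.98), CSTA (4.43 ± 0.95), MS4A3 (4.28 ± 0.95), LILRA5 (4.25 ± 1), NLRP12 (4.24 ± 0.91), FPR1 (4.06 ± 0.96) and LYZ (2.16 ± 0.52), and at CCR6 (2.24 ± 0.58), IFNG (2.17 ± 0.52) and KLRB1 (1.61 ± 0.39). AQP9 was at 23.5 ± 18.5 CPM in memory and 1.65 ± 2.58 in naive cells (SD, n = 4 each, adjusted p 0.00985). Memory cells were lower at OMG (-3.83 ± 0.94), KRT73 (-3.69 ± 0.88), KRT72 (-3.41 ± 0.76), GLYATL1 (-2.90 ± 0.58), CD248 (-2.81 ± 0.61), CRTAM (-2.67 ± 0.59) and CCR7 (-0.73 ± 0.17). Of 12 monocyte marker genes, 1 rose and 0 fell (6 and 0 alone), with a median of 1.67 (camera adjusted p 2.19e-06, 0.0681 estimated). The naive T cell list stood lower in camera, adjusted p 2.34e-05, 0.0681 estimated, with 0 genes up and 1 down of 16 (0 and 3 alone) and a median of -0.46. Among 13 Th17 genes the median was 1.12, and 2 were called up and 0 down (3 and 0 alone) (camera adjusted p 1.69e-04, 0.0681 estimated). Of 18 memory and effector T cell genes, 1 rose and 0 fell (4 and 1 alone), with a median of 0.34 (camera adjusted p 0.00163, 0.0681 estimated). Among 21 cytokine and chemokine genes the median was 1.08, and 1 were called up and 0 down (4 and 1 alone) (camera adjusted p 9.51e-05, 0.0681 estimated). In H3K4me2, 117 promoters were called higher and 101 lower, and the total ran from 7 (without donor 1 or 3) to 252 (without donor 4). The counts were 487 and 98 without the libraries in doubt and 254 and 197 with donor as a block. Other settings gave 3 (input) to 567 (loess), 50.2% to 71.4% higher. Of 18 followed genes, 0 stayed called with each donor left out and 13 without the libraries in doubt.

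H3K4me3 at rest was higher in memory cells at FPR2 (4.38 ± 0.97), NCF4 (3.39 ± 0.68), PRR5L (3.32 ± 0.69), ETV1 (1.96 ± 0.31), LPGAT1 (1.49 ± 0.24) and WEE1 (1.28 ± 0.21). It was lower at BEND5 (-3.25 ± 0.66), GNAI1 (-2.27 ± 0.42), SEMA3A (-1.78 ± 0.34), LEF1-AS1 (-1.53 ± 0.26) and DACT1 (-1.41 ± 0.3). The naive T cell list stood lower in camera, adjusted p 5.06e-08, 0.0432 estimated, with 0 genes up and 0 down of 16 (0 and 9 alone) and a median of -0.67. Of 18 memory and effector T cell genes, 0 rose and 0 fell (7 and 0 alone), with a median of 0.73 (camera adjusted p 1.17e-07, 0.0327 estimated). Among 12 monocyte marker genes the median was 0.99, and 0 were called up and 0 down (1 and 0 alone) (camera adjusted p 2.74e-04, 0.142 estimated). In H3K4me3, 11 promoters were called higher and 10 lower, and the total ran from 0 (without donor 3) to 39 (without donor 1). The counts were 428 and 406 without the libraries in doubt and 93 and 26 with loess. By setting the total ran from 0 (weights) to 119 (loess), 6.25% to 78.2% higher. Here 0 of 13 followed genes stayed called with each donor left out and 13 without the libraries in doubt. H3K27me3 had 0 calls between the resting subsets (limma voom), with 932 promoters at an unadjusted p under 0.05 and 0 (9 of them) to 2 (loess) with other settings.

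At D1 in H3K4me2, memory cells were higher at NCF4 (2.85 ± 0.59), ETV1 (1.69 ± 0.34), DNAI2 (1.5 ± 0.3), CDKN2B (1.33 ± 0.28), CXCR6 (1.30 ± 0.26) and ASB2 (1.05 ± 0.2) and lower at GPR125 (-2.17 ± 0.46), EVA1A (-1.85 ± 0.37), MIR365A (-1.61 ± 0.34) and ASIC1 (-1.12 ± 0.24). Adjusted by the change in input, MIR365A turned direction. The total of 10 ran from 0 (without donor 3) to 12 (without donor 4), and it was 46 with donor as a block and 0 without the libraries in doubt (668 there at an unadjusted p under 0.05, limma voom). Other settings gave 0 (3 of them) to 158 (weights), 34.8% to 61.5% higher. The memory and effector T cell list stood higher in camera, adjusted p 2.26e-05, 0.0309 estimated, with 1 genes up and 0 down of 18 (7 and 0 alone) and a median of 0.26. Among 16 naive T cell genes the median was -0.30, and 0 were called up and 0 down (0 and 1 alone) (camera adjusted p 2.46e-04, 0.0971 estimated). At D5 memory cells were higher at IL26 (2.84 ± 0.71), IL9 (2.54 ± 0.58), CCR6 (2.38 ± 0.6), KIAA0319L (1.77 ± 0.31), PYHIN1 (1.5 ± 0.38) and TIGIT (1.48 ± 0.36) and lower at DNTT (-3.53 ± 0.92), KRT1 (-2.92 ± 0.71), ADORA1 (-2.76 ± 0.63), IRF8 (-1.37 ± 0.27), KDM6B (-0.94 ± 0.23) and TCF7 (-0.84 ± 0.17). Of 13 Th17 genes, 2 rose and 0 fell (5 and 0 alone), with a median of 0.83 (camera adjusted p 2.11e-04, 0.0782 estimated). Among 18 memory and effector T cell genes the median was 0.37, and 2 were called up and 0 down (4 and 0 alone) (camera adjusted p 2.93e-04, 0.0782 estimated). The developmental regulator list stood lower in camera, adjusted p 2.74e-07, 0.0782 estimated, with 0 genes up and 3 down of 26 (0 and 15 alone) and a median of -1.02. In windows of 2.5 kb radius these genes held 0.0654% to 0.122% of reads in the naive and 0.0292% to 0.0513% in the memory libraries, against 0.0784% to 0.0992% in input, and the naive library of donor 2 was in doubt. Among 20 early activation genes the median was 0.36, and 1 were called up and 1 down (5 and 1 alone) (camera adjusted p 0.00136, 0.0782 estimated). At D5, 82 promoters were called higher and 313 lower, and the total ran from 12 (without donor 3) to 77 (without donor 1). The counts were 61 and 200 without the libraries in doubt, 55 and 503 with median ratios and 60 and 530 unscaled. Settings moved the total from 0 (input) to 1957 (other window), 9.86% to 61.9% higher. Here 0 of 12 followed genes stayed called with each donor left out and 8 without the libraries in doubt. At D14 limma voom called 0 promoters, with 389 at an unadjusted p under 0.05.

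H3K4me3 had 0 calls between the subsets at D1, D5 and D14 (limma voom), with 1926, 653 and 160 promoters at an unadjusted p under 0.05, and with donor as a block 1 at D1. Other settings gave 0 (4 of them) to 221 (weights), 63.3% to 92% higher at D1, 0 (8 of them) to 69 (2 groups), 40.6% to 43.1% higher at D5 and 0 at D14. For D1 and then for D5, 2 lists each follow. Of 18 memory and effector T cell genes, 0 rose and 0 fell (8 and 0 alone), with a median of 1.10 (camera adjusted p 4.02e-05, 0.106 estimated). The Th17 list stood higher in camera, adjusted p 4.02e-05, 0.142 estimated, with 0 genes up and 0 down of 13 (5 and 0 alone) and a median of 1.60. Among 18 memory and effector T cell genes the median was 0.49, and 0 were called up and 0 down (3 and 0 alone) (camera adjusted p 1.14e-08, 0.0145 estimated). The Th17 list stood higher in camera, adjusted p 1.78e-07, 0.0593 estimated, with 0 genes up and 0 down of 13 (3 and 0 alone) and a median of 1.12. H3K27me3 at D1 was higher in memory cells at IRF8 (1.65 ± 0.26), MTA3 (2.27 ± 0.39), AK5 (2.07 ± 0.41), CYTIP (2.04 ± 0.39) and SELP (1.92 ± 0.34) and lower at ACTN4 (-2.5 ± 0.34), E2F2 (-1.95 ± 0.37) and CLCF1 (-1.76 ± 0.35). At D1, 8 promoters were called higher and 8 lower, and the total ran from 0 (without donor 2 or 3) to 4 (without donor 4). The counts were 9 and 3 unscaled and 1 and 2 with loess. Across settings it ran from 0 (other window) to 200 (weights), 20% to 75% higher. Among 11 followed genes, 0 stayed called with each donor left out. Of 16 naive T cell genes, 0 rose and 0 fell (3 and 0 alone), with a median of 1.10 (camera adjusted p 2.23e-07, 0.119 estimated). At D5 IRF8 (2.43 ± 0.26) and ST3GAL5 (2.16 ± 0.37) were the 2 promoters called, both higher in memory cells. The total was 4 with donor as a block and ran from 1 (without donor 1 or 2 or 3) to 2 (without donor 4), and with other settings from 1 (unscaled or other window) to 124 (weights), 86.3% to 100% higher. The naive T cell list stood higher in camera, adjusted p 1.35e-06, 0.0578 estimated, with 0 genes up and 0 down of 16 (1 and 0 alone) and a median of 0.56.

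The change after activation differed between the subsets by day at 3 promoters. In H3K27me3 it was IRF8 (chromosome 16, 85930274 to 85938817, hg19, interaction adjusted p 0.0351), in H3K4me2 NCF4 (0.0334) and FUT7 (0.0258), the last 2 named after their values were seen. H3K27me3 at IRF8 moved by -0.86 ± 0.26, -1.20 ± 0.26 and 0.43 ± 0.25 in naive cells at D1, D5 and D14, and by 0.67 ± 0.25, 1.11 ± 0.25 and 0.78 ± 0.27 in memory cells. At D5 it stood at 36 ± 4.21 CPM in naive and 196 ± 17.4 in memory cells (SD, n = 4 each, adjusted p 9.42e-06). H3K4me3 at IRF8 moved by 1.26 ± 0.31 in naive and 0.14 ± 0.38 in memory cells at D5, a difference that did not pass in H3K4me3, and H3K4me2 differed between the subsets by -1.37 ± 0.27. H3K4me2 at NCF4 was 3.05 ± 0.59 higher in memory cells at rest and 0.28 ± 0.2 at D5, after a change of 3.85 ± 0.57 in naive and 1.09 ± 0.25 in memory cells. At FUT7 the difference went from 3.52 ± 0.57 at rest to 0.32 ± 0.36 at D5. H3K4me3 had 0 promoters with an interaction (limma voom), with 1002 at an unadjusted p under 0.05. The interaction totals of 2 in H3K4me2 and 1 in H3K27me3 became 143 and 0 with donor as a block and 95 and 0 without the libraries in doubt. They ran from 0 (without donor 1 or 2 or 3) to 72 (without donor 4) in H3K4me2 and from 0 (without donor 1 or 2 or 4) to 2107 (without donor 3) in H3K27me3.

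**Figure D3:**
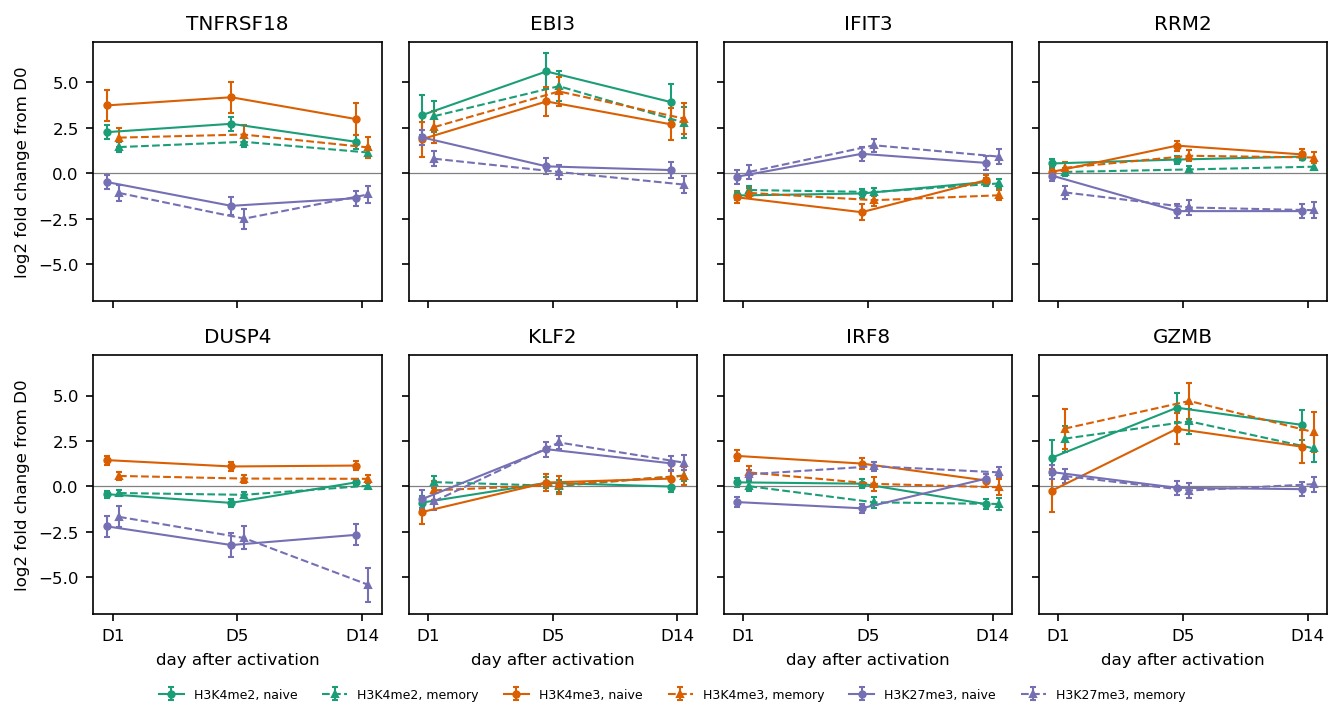
Lines show the log2 fold change from D0 on the y axis at D1, D5 and D14 on the x axis for the promoters of 8 genes, by mark (color) and subset (solid naive, dashed memory), with bars of 1 standard error from limma voom. H3K27me3 at IRF8 fell by 1.20 in naive cells at D5 and rose by 1.11 in memory cells, while at RRM2 and DUSP4 it fell in both.

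How much of the difference between memory and naive cells at rest was left after activation was asked with slopes across genes, which are not independent replicates. D0 came from 2 donors and the later day from the others, over the 6 such splits. The slope of D0 on D0 itself had a mean (range) of 0.12 (0.049 to 0.25) in H3K4me2, 0.1 (-0.069 to 0.27) in H3K4me3 and -0.19 (-0.47 to -0.021) in H3K27me3. The ratios to it therefore spread widely. In H3K4me2 they were 2.21 (0.668 to 4.28) at D1, 0.315 (-2.96 to 4.99) at D5 and 0.455 (-0.785 to 2.52) at D14. In H3K4me3 they were 0.849 (-1.8 to 6.01), -0.163 (-3.71 to 2.1) and -0.662 (-4.44 to 2.18), and in H3K27me3 -0.967, -0.526 and -1.96. Over the 218 promoters called at rest in H3K4me2, which were selected on the same libraries, the ratios were 0.581, 0.136 and 0.0392, and over the 21 in H3K4me3 0.584, 0.19 and 0.101.

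Changes in the marks were related across genes by Spearman correlation (range with a donor left out). H3K4me2 and H3K4me3 moved together at D5 and D14, with 0.78 (0.46 to 0.8) and 0.76 (0.48 to 0.8) in naive and 0.52 (0.36 to 0.63) and 0.7 (0.57 to 0.76) in memory cells, against 0.22 (0.053 to 0.36) and 0.21 (0.052 to 0.43) at D1. At naive D5, 644 promoters rose in both marks (169 for independent lists), 1021 fell in both (220), and 0 and 2 were opposite. H3K4me3 and H3K27me3 there both rose at 61 (20.2), fell at 22 (5.45) and were opposite at 7 and 3. For H3K4me2 and H3K27me3 these were 241 (87.6), 38 (15.3), 7 and 4. With loess H3K27me3 had 2 rises, not 471, so these overlaps depend on scaling. H3K27me3 correlated with H3K4me2 by 0.49 (0.42 to 0.55) at naive D5 and 0.078 (0.0047 to 0.18) at memory D5. With H3K4me3 it had 0.43 (0.33 to 0.39) and 0.058 (-0.026 to 0.085). The differences between memory and naive cells in H3K4me2 and H3K27me3 had -0.07 (-0.21 to -0.027) at rest and -0.19 (-0.22 to -0.083) at D1. At D5 and D14 they had 0.08 (-0.01 to 0.12) and 0.077 (-0.081 to 0.096). TNFRSF18 gained H3K4me3 in naive cells at D5 (4.18 ± 0.86) while H3K27me3 moved by -1.79 ± 0.49 there (limma voom adjusted p 0.0601 with donor as a block, not called) and by -2.5 ± 0.55 in memory cells. RRM2 moved by 1.52 ± 0.28 in H3K4me3 and -2.08 ± 0.4 in H3K27me3 in naive cells. IFIT3 moved by -1.48 ± 0.3 in H3K4me3 and 1.54 ± 0.37 in H3K27me3 in memory cells at D5.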

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

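Of the tests in this part, 4 were chosen after the result they measure was seen: both on the fall of H3K27me3 at memory D14, the count of monocyte markers in both H3K4 marks and the loess offsets at naive D1. The other tests were written before their own results, but the fit without libraries in doubt and the share limit at D0 were set after the data were examined. In groups of 4 libraries, a library stood apart when its gap to the nearest other, divided by the range of the group, passed the limit of the Dixon test for 4 values. Chance gives about 5% of groups. Past it were 6 of 100 groups among library measures and 36 of 594 among followed genes (6.06%), close to that rate. Among library measures they were the share of reads in the top window in H3K4me2 naive D0 (0.872), H3K4me2 memory D0 (0.871) and H3K4me3 naive D14 (0.86) and the share in CpG island windows in H3K4me3 naive D14 (0.834), input naive D5 (0.95) and input memory D0 (0.964).

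Among followed genes in H3K4me2, 1 donor stood apart for DAD1 in naive D1 (0.855), EGR2 in naive D1 (0.846), EBI3 in naive D5 (0.858), CCL1 in naive D0 (1), HOXA9 in naive D0 (0.9), CLDN2 in naive D14 (0.846), TSGA13 in memory D1 (0.856), KHDRBS2 in memory D0 (0.833), CPA6 in memory D1 (0.969), CEND1 in memory D0 (1), TEAD4 in memory D0 (0.932), LILRA5 in naive D0 (1), CD248 in memory D0 (0.913), OMG in memory D0 (1), OMG in naive D0 (0.858), DNAI2 in memory D1 (0.902) and KRT1 in naive D5 (0.843). In H3K4me3 this held for FAM65B in naive D1 (0.865), LINC00521 in naive D0 (1), AHRR in naive D5 (0.951), EBI3 in memory D5 (0.884), IL22 in memory D0 (1), ALDH1A1 in memory D5 (0.905), LONRF2 in memory D0 (1), FPR2 in naive D0 (1) and LPGAT1 in memory D0 (0.845). In H3K27me3 it held for SIX3 in naive D0 (0.895), MYCBP2 in naive D1 (0.832), XPO1 in naive D1 (0.884), ZNF217 in naive D1 (0.882), DUSP4 in naive D5 (0.901), WEE1 in naive D14 (0.857), PTAFR in memory D5 (0.927), TNFRSF18 in memory D0 (0.872), ENO2 in memory D5 (0.882) and E2F2 in memory D1 (0.859). A ratio of 1 means that the other 3 libraries had the same value, likely no read as totals differ. Fold changes against these groups rest on that floor.

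The change after activation differed between naive and memory cells, by the interaction test, for FUT7 (adjusted p 0.0258) and NCF4 (0.0334) in H3K4me2 and IRF8 (0.0351) in H3K27me3. In H3K27me3 there were 0 with donor as a block and 0 without the libraries in doubt, so IRF8 was not called in either.

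H3K27me3 at memory D14 was called lower than at D0 at 4556 promoters, with a median log2 fold change of -2.8. Without the memory D14 library of donor 4, which had the most windows at 0, 10 promoters were called in either direction. Of the promoters first called lower, 2380 of 4556 were still lower, and their median was -0.028, which argues against a loss of the mark of the size first measured. One library of low complexity may therefore account for the fall. A smaller loss stays open, as 2 libraries were left at D14.

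Monocyte marker promoters were higher in memory than naive cells at rest, and a candidate explanation is monocytes among the memory cells. Of 12 markers tested in both marks, 10 were higher in both H3K4me2 and H3K4me3, with medians of 1.67 and 0.995, against -0.07 for B cell markers and 0.734 for NK cell markers in H3K4me2. LYZ stood at 37.1 CPM in memory and 12 in naive cells, 1 of the 12 markers was above the median promoter in H3K4me3 of naive cells at rest, and no other list holds a marker. The libraries in doubt were argued against as the source, since without them the median rose to 2.39. Its quartiles were then 1.74 and 3.93, against 1.08 and 2.88 with all. That fit kept only the H3K4me2 memory D0 libraries of donors 1 and 4. Complexity itself was not measured, only empty windows and the share of CpG island reads. Expression of these genes by memory T cells stays open, and the labels name no sort or gate that would remove monocytes.

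H3K27me3 at developmental regulators rose in naive cells at D1, with a median of 1.23 over 30 genes (quartiles 1.08 and 1.57). Weaker immunoprecipitation in the D0 libraries may explain it, as the list held 0.146% to 0.456% of promoter reads at D0 and 0.497% to 0.663% at D1. Loess offsets gave 91 calls (66 falls) against 4168 (2149 falls) and a median of 0.247 (quartiles -0.02 and 0.741). Fold change followed abundance across genes (Spearman correlation 0.74). The offsets remove this by construction, and with it any real gain at the most marked promoters. The falls called share this doubt. In the 2 donors with over 0.3% at D0 the median was 0.392 (quartiles 0.135 and 0.583), between the bounds set for a gain and for none, so a gain of the mark and weaker immunoprecipitation cannot be told apart here.

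Other splits of the 8 libraries of each comparison into 4 and 4 (35 in all, or 35 splits into 3 and 4 of 7) were tested the same way. As the donors pair the libraries, the real split is compared with those that part every pair, and with 8 of these no share under 0.05 can be had. The other splits keep both libraries of at least 1 donor on 1 side, so differences between donors enter them. Brackets give the real count, the highest count of another split and the highest of another paired split. In H3K4me2 only the real split of all 35 called as many promoters for naive D1 (712, 28, 10), naive D5 (6881, 1659, 250), naive D14 (1820, 510, 1), memory D5 (2459, 1285, 0), memory D14 (1887, 54, 1), subsets D0 (218, 181, 2), subsets D1 (10, 1, 0) and subsets D5 (395, 1, 1). In H3K4me3 only the real split of all 35 called as many promoters for naive D5 (2010, 222, 2), memory D5 (107, 3, 0) and memory D14 (694, 102, 1). In H3K27me3 only the real split of all 35 called as many promoters for naive D1 (4168, 2821, 0), naive D5 (562, 22, 0), naive D14 (104, 0, 0), memory D1 (4, 0, 0), memory D5 (460, 0, 0), subsets D1 (16, 0, 0), subsets D5 (2, 0, 0) and subsets D14 (4403, 4351, 3543). More than 1 of all 35 splits did for H3K4me2 memory D1 (2 splits, 1168, 1356, 1356), H3K4me3 naive D1 (2 splits, 256, 354, 110), H3K4me3 naive D14 (2 splits, 302, 349, 0), H3K4me3 subsets D0 (12 splits, 21, 2735, 9) and H3K27me3 memory D14 (3 splits, 4867, 5501, 5501). Comparisons with 0 calls, matched by all 35 splits, had a highest other of 3 (H3K4me2 subsets D14), 340 (H3K4me3 memory D1), 728 (H3K4me3 subsets D1), 1538 (H3K27me3 subsets D0), 1863 (input naive D1), 1 (input naive D5), 4 (input memory D1), 66 (input subsets D0), 2997 (input subsets D1) and 1 (input subsets D5), and of 0 in the remaining ones. For the interaction, 100 splits drawn within each day without regard to donor, the real one included, gave as many calls 4 times in H3K4me2 (real 2, highest other 103), 100 times in H3K4me3 (real 0, highest other 831), 3 times in H3K27me3 (real 1, highest other 111) and 100 times in input (real 0, highest other 566). Splits with many more calls than the real one point to a structure of the libraries other than their groups. Such were subsets D0 in H3K4me3 and H3K27me3 and subsets D1 in input. At H3K27me3 memory D14 the excess was small.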

How the results depend on the processing

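Sample quality weights and the fit without libraries in doubt were chosen after the data were examined. All other settings were chosen before. Changes are counts of called promoters that moved by more than 1.5 times. DESeq2 Wald tests, named before the data were examined, were not run. The cause of the changes was not tested, except that subtracting input adds the spread of the input libraries by construction.

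With median-of-ratios size factors, 35 of 44 counts kept within 1.5 times. H3K4me2 had 0 at subsets D1 and 19 at interaction. H3K4me3 had 406 at naive D1, 32 at subsets D0 and 1 at interaction. H3K27me3 had 366 at naive D5, 1 at memory D1 and 10 at subsets D1. input had 1 at naive D5. Among 62 list results 1 lost and 0 gained their call, and 22 of 326 followed genes lost it. The median of all genes moved by more than 0.1 log2 in 1 of 30 comparisons, by up to 0.13.

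With no scaling factors, 34 of 44 counts kept within 1.5 times. H3K4me2 had 36 at interaction. H3K4me3 had 1 at interaction. H3K27me3 had 292 at naive D5, 0 at memory D1, 281 at memory D5, 240 at memory D14, 1 at subsets D5, 0 at subsets D14 and 0 at interaction. input had 1 at naive D5. Calls were lost for 0 and gained for 0 of 62 list results, and lost for 23 of 326 followed genes. The median of all genes moved by more than 0.1 log2 in 16 of 30 comparisons, by up to 0.3.

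With loess offsets, 20 of 44 counts kept within 1.5 times. H3K4me2 had 357 at naive D1, 3301 at naive D5, 1127 at naive D14, 1136 at memory D14, 567 at subsets D0, 0 at subsets D1, 51 at subsets D5 and 11 at interaction. H3K4me3 had 544 at naive D1, 1081 at naive D5, 14 at memory D1, 61 at memory D14, 119 at subsets D0 and 3 at interaction. H3K27me3 had 91 at naive D1, 18 at naive D5, 46 at naive D14, 1 at memory D1, 15 at memory D5, 2298 at memory D14, 2 at subsets D0, 3 at subsets D1, 0 at subsets D14 and 0 at interaction. Among 62 list results 9 lost and 3 gained their call, and 105 of 326 followed genes lost it. The median of all genes moved by more than 0.1 log2 in 11 of 30 comparisons, by up to 0.6.

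With no filter on low counts, 27 of 44 counts kept within 1.5 times. H3K4me2 had 373 at naive D1, 614 at memory D1, 17 at subsets D1, 658 at subsets D5 and 6 at interaction. H3K4me3 had 863 at naive D5, 26 at naive D14, 10 at subsets D0 and 25 at subsets D1. H3K27me3 had 13 at memory D1, 4 at subsets D1 and 0 at interaction. input had 11 at naive D1, 1 at naive D5, 3 at memory D1, 3 at subsets D0 and 42 at subsets D1. Calls were lost for 1 and gained for 0 of 62 list results, and lost for 34 of 326 followed genes.

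With the other window, 20 of 44 counts kept within 1.5 times. H3K4me2 had 191 at naive D1, 251 at memory D1, 575 at memory D14, 432 at subsets D0, 71 at subsets D1, 1957 at subsets D5 and 37 at interaction. H3K4me3 had 146 at naive D1, 183 at naive D14, 207 at memory D5, 1335 at memory D14, 33 at subsets D0 and 11 at subsets D1. H3K27me3 had 2628 at naive D1, 347 at naive D5, 314 at naive D14, 2 at memory D1, 197 at memory D5, 2959 at memory D14, 0 at subsets D1, 1 at subsets D5, 2267 at subsets D14 and 0 at interaction. input had 30 at naive D5. Among 62 list results 1 lost and 0 gained their call, and 79 of 324 followed genes lost it. The direction was reversed for IL23R (-0.0154, H3K4me2 naive D1) and CSF1R (0.49, H3K4me2 memory D14).

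With all promoter windows, 30 of 44 counts kept within 1.5 times. H3K4me2 had 373 at subsets D0, 16 at subsets D1 and 4 at interaction. H3K4me3 had 21 at naive D1, 334 at naive D5, 12 at naive D14, 1 at memory D1, 281 at memory D5 and 1 at subsets D1. H3K27me3 had 63 at naive D14, 1 at memory D1, 3 at subsets D1, 4 at subsets D5 and 0 at interaction. Of 326 followed genes 53 lost their call.

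With only the groups of the contrast in the fit, 23 of 40 counts kept within 1.5 times. H3K4me2 had 38 at naive D1, 557 at memory D1, 1352 at memory D5, 36 at subsets D0 and 193 at subsets D5. H3K4me3 had 1 at naive D1, 4 at memory D5, 140 at memory D14, 2 at subsets D0 and 69 at subsets D5. H3K27me3 had 1990 at naive D1, 0 at memory D1, 0 at memory D14, 61 at subsets D1, 23 at subsets D5 and 0 at subsets D14. input had 27 at naive D5. Among 62 list results 3 lost and 0 gained their call, and 122 of 310 followed genes lost it.

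With the change in input subtracted, 11 of 33 counts kept within 1.5 times. H3K4me2 had 0 at naive D1, 30 at naive D5, 3 at naive D14, 9 at memory D1, 202 at memory D5, 4 at memory D14, 3 at subsets D0, 0 at subsets D1, 0 at subsets D5 and 0 at interaction. H3K4me3 had 1 at naive D1, 0 at naive D5, 0 at naive D14, 30 at memory D5, 0 at memory D14, 1 at subsets D0 and 1 at subsets D1. H3K27me3 had 1043 at naive D1, 0 at naive D5, 42 at naive D14, 165 at memory D5 and 0 at interaction. Calls were lost for 18 and gained for 1 of 62 list results, and lost for 260 of 326 followed genes. The direction was reversed for DAD1 (0.47, H3K4me2 naive D1), MYC (1.30, H3K4me2 naive D1), EGR2 (0.31, H3K4me2 naive D1), FOS (-0.53, H3K4me2 memory D1), CPA6 (0.80, H3K4me2 memory D1), IFIT2 (0.0492, H3K4me2 memory D14) and MIR365A (0.52, H3K4me2 subsets D1). The Treg list at H3K4me2 naive D1 turned direction, at a camera adjusted p of 0.977.

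With donor as replicate block, 28 of 44 counts kept within 1.5 times. H3K4me2 had 1091 at naive D1, 2139 at memory D1, 2845 at memory D14, 451 at subsets D0, 46 at subsets D1 and 143 at interaction. H3K4me3 had 212 at memory D14 and 1 at subsets D1. H3K27me3 had 362 at naive D5, 28 at memory D14, 4 at subsets D5, 0 at subsets D14 and 0 at interaction. input had 1 at naive D1, 1 at naive D5 and 10 at memory D5. Among 62 list results 0 lost and 0 gained their call, and 23 of 326 followed genes lost it. Counts not listed moved by less than 1.5 times, with single calls lost and gained.

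With sample quality weights, 19 of 44 counts kept within 1.5 times. H3K4me2 had 14 at subsets D0, 158 at subsets D1, 644 at subsets D5 and 0 at interaction. H3K4me3 had 82 at naive D1, 744 at naive D5, 143 at naive D14, 5 at memory D1, 12 at memory D5, 326 at memory D14, 0 at subsets D0, 221 at subsets D1 and 58 at subsets D5. H3K27me3 had 2237 at naive D5, 448 at naive D14, 3465 at memory D1, 3153 at memory D5, 33 at memory D14, 200 at subsets D1, 124 at subsets D5 and 0 at subsets D14. input had 61 at naive D5, 1 at naive D14, 6 at memory D5 and 1 at subsets D5. Calls were lost for 3 and gained for 0 of 62 list results, and lost for 85 of 326 followed genes.

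With the libraries in doubt left out, 17 of 44 counts kept within 1.5 times. H3K4me2 had 92 at naive D1, 3 at memory D1, 1406 at memory D5, 470 at memory D14, 585 at subsets D0, 0 at subsets D1, 261 at subsets D5 and 95 at interaction. H3K4me3 had 4458 at naive D5, 1429 at naive D14, 206 at memory D5, 256 at memory D14, 834 at subsets D0, 11 at subsets D5 and 2 at interaction. H3K27me3 had 7054 at naive D1, 1607 at naive D5, 409 at naive D14, 996 at memory D5, 10 at memory D14, 45 at subsets D1, 6 at subsets D5, 0 at subsets D14 and 0 at interaction. input had 70 at naive D5, 5 at memory D5 and 1 at memory D14. Among 62 list results 1 lost and 1 gained their call, and 75 of 326 followed genes lost it. The H3K27me3 comparisons without memory D14 held no such library, nor did H3K4me2 naive D14 and subsets D14 or H3K4me3 subsets D5, so their counts moved only through the fit shared with the other groups.

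Leaving out each donor in turn, the counts ran over these ranges. H3K4me2 ran 29 to 1141 at naive D1, 3138 to 6849 at naive D5, 215 to 2099 at naive D14, 4 to 3022 at memory D1, 816 to 2191 at memory D5, 78 to 2726 at memory D14, 7 to 252 at subsets D0, 0 to 12 at subsets D1, 12 to 77 at subsets D5, 0 to 1 at subsets D14 and 0 to 72 at interaction. H3K4me3 ran 6 to 550 at naive D1, 1 to 2577 at naive D5, 0 to 1316 at naive D14, 0 to 7 at memory D1, 2 to 105 at memory D5, 1 to 1801 at memory D14, 0 to 39 at subsets D0 and 0 to 1 at interaction. H3K27me3 ran 0 to 6884 at naive D1, 2 to 529 at naive D5, 0 to 24 at naive D14, 0 to 1 at memory D1, 78 to 287 at memory D5, 0 to 6248 at memory D14, 0 to 4 at subsets D1, 1 to 2 at subsets D5, 0 to 5224 at subsets D14 and 0 to 2107 at interaction. input ran 0 to 89 at naive D1, 0 to 21 at naive D5, 0 to 2 at memory D1, 0 to 161 at memory D5 and 0 to 3 at subsets D1. Of 326 followed genes, 151, 216, 225 and 103 lost their call without donors 1, 2, 3 and 4, and ARHGAP32 in H3K4me3 at naive D5 ran from -3.7 without donor 1 to 1.12, a reversed direction, without donor 2. List results lost numbered 8, 1, 1 and 2.

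With a correlation estimated from the libraries, 43 list results lost their camera call, and with fry 10 lost and 3 gained it. The retention ratio of H3K4me2 moved with no filter on low counts to -13.7 at D1, 29.7 at D5 and 7.93 at D14. At D1 it moved to -1.67 with the other window and to 0.581 with genes called at rest. The divisor (the slope at rest) was 0.014 without the filter, 0.009 with the other window, 0.91 over genes called at rest and 0.12 otherwise. With genes called in either mark, the correlation of H3K4me2 and H3K4me3 moved to 0.84 at memory D5 and 0.72 at subsets D0. That of H3K4me2 and H3K27me3 moved to 0.58 at naive D5 and -0.44 at subsets D0. That of H3K4me3 and H3K27me3 moved to 0.54 at naive D5 (0.47 with the other window), -0.19 at memory D5 and -0.17 at subsets D0. Pearson correlation moved none of the 9 relations by as much as their standard deviation over leaving out each donor. In simulated counts for naive D5, 40% of 2-fold changes were found in H3K4me2, 9.09% in H3K4me3 and 1.49% in H3K27me3. Only 939 of 3336 real H3K4me2 falls there reached 2-fold, so the simulated shares need not hold for these data. Depth was not varied.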
